A study of Homo sapiens with 6 samples.

How the data were processed

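Total RNA was extracted with Trizol from FaDu cells treated with the compound BB608 or with its vehicle DMSO, per the labels. Libraries were made with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols, so transcripts without a poly(A) tail were also sequenced. The series holds 6 libraries in 2 groups, with 3 biological replicates per group per the series' design text. Doses and treatment times are not given in the sources used here.

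Per the submitters' processing notes, the tools were TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff, with the human genome build hg19. The gene annotation is not given in the sources used here. The values analysed come from a table of the authors' own comparison, with 1 row per coding sequence and 1 FPKM value per group, pooled by the authors over each group's libraries. The deposited column names call both groups a subset, a word the sources used here do not explain. The authors' deposited table also gives the log2 fold of BB608 over DMSO, a test statistic that serves as a score, a p-value and a q-value per row. Its log2 fold matched the log2 ratio of its FPKM values to within 4.72e-05 in tested rows above 0.001 FPKM. Its q matched a Benjamini-Hochberg adjustment of its p-values over all tested rows to within 5.23e-07.

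The design fixed before the data were examined foresaw limma on values per library and, for a table holding only the authors' comparison, a description with no test of its own. The second case applied. No library could be left out, no replicates could be compared, and camera, fry and an estimated inter-gene correlation could not be run, because all of these need values per library. Sequencing depth is unknown, since FPKM values pooled over a group carry no read counts. A coding sequence was called changed where the authors' q was under 0.05, with no bound on the fold. Cuffdiff's smallest p was 5e-05, which corresponds to a q of 0.0154, so the q of most calls sits at that floor.

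An error was derived for each log2 fold. The normal quantile of the authors' p divided by the absolute statistic had a median of 1.73 over 28406 rows, with quartiles of 1.63 and 1.77. The fold divided by the statistic and by that median is called the implied SE here. It is an approximation and covers only the spread that the authors' model estimated.

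Cufflinks divides the reads of a gene among its coding sequences, and this division is uncertain where sequences overlap. FPKM values were therefore also summed over all coding sequences of a gene name, giving a gene sum. A gene was kept for gene lists when it had a tested coding sequence, no row of failed status, a gene sum of at least 1 FPKM in the higher group and a single gene name, which left 10859 genes.

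The 35 gene lists were fixed before the data were examined. For each list, the median log2 fold of the gene sums was placed among 10000 random lists matched on mean expression in 20 bins. A list of at least 5 kept genes was said to stand apart when its median lay below percentile 2.5 or above percentile 97.5. This describes these values and is not a test across replicates. Of 32 lists about 1.6 would stand apart by chance if the matching were exact and genes varied independently. The share among lists of 20 genes drawn at random, given with the simulated data, was higher. Some lists share members, such as PTGS2 in the NF-kB and aryl hydrocarbon receptor lists, so lists that stood apart are not all separate findings. Members past the authors' q were counted, as were members past a q recomputed from the deposited p-values over the list alone.

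Named genes followed a rule fixed beforehand. It took the 12 largest falls and the 12 largest rises with a q under 0.05 and at least 1 FPKM in the higher group, without short RNAs or merged loci. It added up to 4 called members with the largest folds from each list that stood apart, 2 from any other list with 5 or more calls, and 17 genes named whatever their result. For these 17, the tested coding sequence reported is the most abundant one. Genes named outside this rule are said to have been chosen after their values were seen.

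The calling step was tested on simulated data for this comparison, with 33395 coding sequences given the implied SE and 200 of them changed. It recovered 6% of changes of 0.5 log2, 24% of changes of 1 log2, 52% of changes of 2 log2 and 72% of changes of 3 log2. It called 5 unchanged sequences. The simulated noise and p-values were both normal with the implied SE, so p-values of unchanged sequences were uniform. The authors' p-values were under 0.05 in 1140 coding sequences, against 1723.7 for uniform p-values. The simulated shares need not hold for the authors' test. Of 200 lists of 20 kept genes drawn at random with their observed folds, 7.5% fell outside the middle 95% of random lists. Every such list lay above that range once 0.3 log2 was added to its median. Smaller shifts were not tried, and genes drawn at random need not vary together as members of a fixed list may.

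Alternatives were pseudocounts of 1, 0.1 and 0.01, filters on mean FPKM of 1 and 5, rescaling by the median of log2 ratios, quantile normalization, a fold bound of 1 log2, and several choices added later. Locus coordinates are those of the authors' deposited table, written with starts counted from 1, and mark the whole locus and not the coding exons. Transcript lengths and GC content came from GENCODE release 29 on GRCh38, matched by gene name, with no coordinates taken from it. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.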

Results

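Gene expression was measured by RNA sequencing in FaDu cells, an established line from a squamous cell carcinoma of the hypopharynx and so a head and neck squamous cell carcinoma (HNSCC) line. The question was how BB608, a compound given only by this code name in the sources used here, changes gene expression against the vehicle DMSO. Each group had 3 biological replicates. The authors' deposited table gives 1 pooled FPKM value per group for 82428 coding sequences of 20660 gene names, with no value per library and no depth. Errors below are the SE implied by the authors' statistic and p.

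With BB608, 6 of 23 tested immediate-early and growth factor response genes fell, and 9 of 21 replication-dependent histone genes of a fixed list rose. The largest fall of a called coding sequence was in ATF3, a stress-induced transcription factor, and went from 6.51 FPKM in DMSO to 0.381 FPKM in BB608 in the authors' deposited table, a log2 fold of -4.09 (implied SE 0.48). ATF3 had 4 tested coding sequences, and its gene sum went from 15.1 to 3.45 FPKM, a log2 fold of -2.13. With a pseudocount of 1 the fold of the called sequence was -2.44. SOCS3, a feedback inhibitor of cytokine signalling, went from 31.4 to 10.8 FPKM in the authors' deposited table, a log2 fold of -1.53 (implied SE 0.15). Its other tested coding sequence, not called, was higher in BB608, at 0.893 FPKM in DMSO and 2.80 FPKM in BB608. The SOCS3 gene sum had a log2 fold of -1.24. IL8, which encodes a neutrophil-attracting chemokine, went from 77.2 to 36.0 FPKM in that table. Among 60 tested genes of the replication-dependent histone clusters, 60 were higher in BB608 and 30 rose past the authors' q. By contrast, the authors' deposited table called no change in STAT3, MYC, SOX2 or CD44, which does not show that all of them stayed level.

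In all, 122 of 34474 tested coding sequences had a Cuffdiff q under 0.05 in the authors' deposited table, from 121 genes. Of these, 73 fell and 49 rose. The falls were larger, with a median log2 fold of -0.90 against 0.49 for the rises, and 33 falls and 7 rises reached 1 log2. At an unadjusted p under 0.05 the table held 1140 coding sequences, fewer than the 1723.7 that uniform p-values would give, and of these 519 were lower and 621 higher in BB608. Among coding sequences with a mean of at least 5 FPKM, 38 fell and 45 rose at a recomputed q under 0.05. With normal p-values from the authors' statistic 95 fell and 63 rose, and with quantile normalization as well 114 fell and 46 rose.

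**Figure D1:**
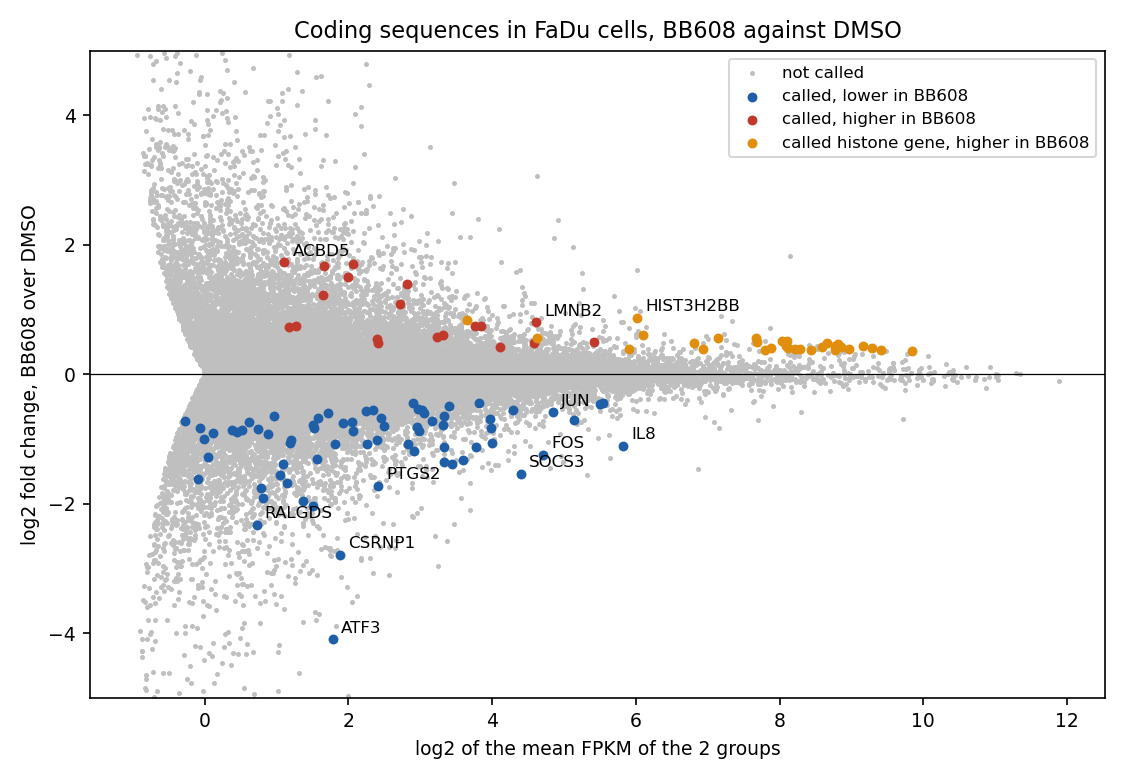
Log2 fold change of BB608 over DMSO (y axis) against log2 of the mean FPKM of the groups (x axis), 1 point per tested coding sequence with at least 1 FPKM in either group. Grey points were not called, blue points fell, red points rose and orange points are histone genes that rose; 881 coding sequences beyond 5 log2 are left out. The called histone genes lie at high FPKM with folds mostly under 1 log2, and among called coding sequences ATF3 has the largest fall.

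Next among the falls was CSRNP1, a transcription factor gene with 1 tested coding sequence, at a log2 fold of -2.79 (implied SE 0.31; q 0.0154) in the authors' deposited table. This is a larger fall than that of the ATF3 gene sum, and with a pseudocount of 1 it was -1.94. CHAC1, a glutathione-degrading enzyme of the stress response, had -2.03, the epithelial transcription factor OVOL1 -1.96 and the costimulatory ligand TNFSF9 -1.91 in the same deposited table. The gene sum of CHAC1, which had 3 tested coding sequences, had -1.06. PTGS2, the inducible cyclooxygenase, had -1.72 (implied SE 0.21), FAM46C -1.68 and ADNP2 -1.61. A pseudocount of 1 understates folds at such low FPKM, and gave -1.12 for TNFSF9, -1.09 for FAM46C and -0.72 for ADNP2. The gene sums of OVOL1, PTGS2 and ADNP2 had -1.78, -1.96 and -1.88. The ATF3 locus spans 212738676 to 212794360 on chromosome 1 of hg19, and the SOCS3 locus spans 76352864 to 76356158 on chromosome 17. RALGDS had -2.32 and NFIB -1.76 for 1 coding sequence each in the authors' deposited table, but their gene sums moved by 0.01 and 0.10. MBNL2 had -1.56 for its coding sequence and -0.32 for its gene sum.

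The largest rises were mostly of single coding sequences within genes that had several. ACBD5, a peroxisomal acyl-CoA binding protein, went from 0.994 to 3.31 FPKM in the authors' deposited table, a log2 fold of 1.73 (implied SE 0.29), against 0.45 for its gene sum. CCDC138 had 1.71, CSTF2 1.67 and SMPD4 1.50 in the deposited table, with gene sums of 0.24, 0.12 and 0.07. ANO6 had 1.40 and PLEC, which encodes the cytolinker plectin, 1.08, with gene sums of 0.68 and 0.19. POLD1, the catalytic subunit of DNA polymerase delta, had 0.75 and a gene sum of 0.21. CHPF, a chondroitin-polymerizing factor, had 1.23 with a gene sum of 1.01. Rises of genes with 1 tested coding sequence were HIST3H2BB at 0.88 (implied SE 0.12), HIST2H3D at 0.83, the lamin gene LMNB2 at 0.80 and the heat shock gene HSPA6 at 0.75 in the authors' deposited table.

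The replication-dependent histone list, fixed before the data were examined, had 9 of 21 members that rose and 12 that were tested and not called. All 21 were higher in BB608, and 17 rose adjusted over the list alone. The list's median log2 fold was 0.39, above every one of 10000 matched random lists, and none of those held as many called genes. The random lists were matched on mean expression and not on the number of tested coding sequences per gene. Coding sequences of genes with 1 were called more often, which limits the comparison of calls. HIST2H2BE had a log2 fold of 0.57 (implied SE 0.10), HIST1H2BJ 0.51, HIST1H2AB 0.50 and HIST1H3H 0.48 in the authors' deposited table. Over all 60 tested histone cluster genes, a set drawn by name after the values were seen, the folds ran from 0.07 to 1.02. Their summed FPKM went from 17672 to 22651, which is 3.60% and 4.51% of all FPKM. Near-identical histone genes share reads, so the fold of any single histone gene is uncertain. After quantile normalization 59 of the 60 were higher.

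The immediate-early and growth factor response list had 6 of 23 tested members that fell and 17 that were not called. Adjusted over the list alone, 13 fell and 1 rose. Its median log2 fold was -0.39, below every matched random list. HBEGF, an EGF receptor ligand, had -1.36 (implied SE 0.22), the phosphatase gene DUSP1 -1.33, the transcription factor gene FOS -1.24 and DUSP5 -0.83 in the authors' deposited table. FOS had 8 tested coding sequences and a gene sum of -0.61. In the list of NF-kB and inflammatory cytokine genes, 2 of 23 tested members fell, PTGS2 and IL8, and 10 fell adjusted over the list alone. The IL8 log2 fold was -1.10 (implied SE 0.10) in the authors' deposited table, and 17 of the list's 20 kept genes were lower in BB608, with a median of -0.45.

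**Figure D2:**
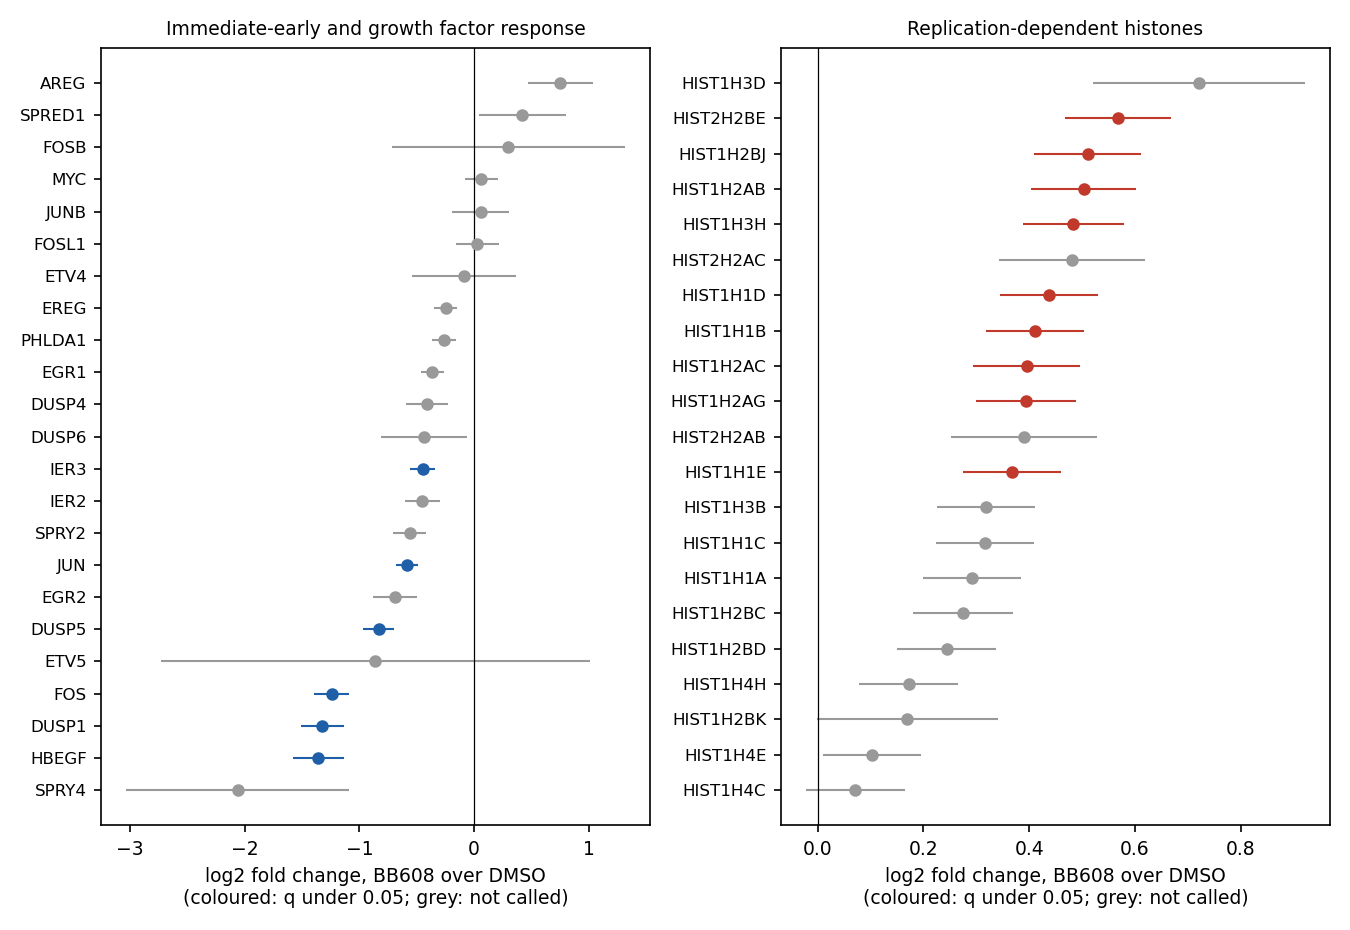
Log2 fold change of BB608 over DMSO (x axis) for the members (y axis) of the immediate-early list and of the replication-dependent histone list. A called member is shown by its coding sequence of lowest q, any other by its tested coding sequence of highest DMSO FPKM. Folds of 5 log2 or more in either direction are not drawn. Bars are 1 implied SE, coloured points had a q under 0.05 in the authors' deposited table and grey points did not. Called members lie to the left of 0 in the first list and to the right in the second.

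Smaller shifts set other lists apart. In the amino acid and integrated stress response list, 4 of 28 tested members fell, namely ATF3, CHAC1, ASNS at -0.71 and PPP1R15A at -0.68 in the authors' deposited table. Adjusted over the list alone, 6 fell and 1 rose, and the median was -0.05. The ASNS gene sum had -0.44, and the list no longer stood apart after quantile normalization. Of 20 tested p53 targets 2 fell, GADD45A at -1.13 and BTG2 at -1.08 in the deposited table, 4 fell adjusted over the list alone, and the median was -0.12. Among 8 tested aryl hydrocarbon receptor targets only PTGS2 fell, 2 fell adjusted over the list alone, and the median was -0.12. NRF2 targets, genes of the antioxidant response, had no call by Cuffdiff's q among 26 tested members, none over the list alone, and a median of -0.07. At an unadjusted p under 0.05 in the authors' deposited table, 4 of them had a coding sequence. Apoptosis regulators had no call by Cuffdiff's q among 18, with 1 fall over the list alone, 4 genes at an unadjusted p under 0.05 and a median of -0.07. They no longer stood apart when each gene was taken by its most abundant coding sequence. Heat shock genes had 1 rise among 17, HSPA6, both over all genes and over the list alone. Their median of 0.10 lay at percentile 97.68, close to the limit of 97.5, and several other settings moved it inside.

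STAT3 targets did not stand apart, with a median log2 fold of -0.01 at percentile 13.28. In this list 3 of 22 tested members fell, both over all genes and adjusted over the list alone. Of 10000 random lists, not matched on the number of tested coding sequences per gene, 7 held as many calls. The 3 members were SOCS3, FOS at -1.24 and PIM1, a kinase gene chosen after its value was seen, at -0.72 in the authors' deposited table. The 23 lists of at least 5 kept genes that did not stand apart, this one included, had medians between -0.05 and 0.11, and 14 of them held no call. Cholesterol synthesis genes, at percentile 2.6, had no call by Cuffdiff's q among 25 tested members, 1 fall adjusted over the list alone and 3 genes at an unadjusted p under 0.05. They stood apart under 3 other settings. Neither the list of G1/S and DNA replication genes nor that of G2/M and mitosis genes had a call by Cuffdiff's q, among 28 and 33 tested members, of which 2 and 3 had an unadjusted p under 0.05. Stemness factors had 1 rise among 15 tested members, NOTCH1, named after its value was seen. Of fibroblast markers 1 gene was kept and of blood and endothelial markers 3, with no call.

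**Figure D3:**
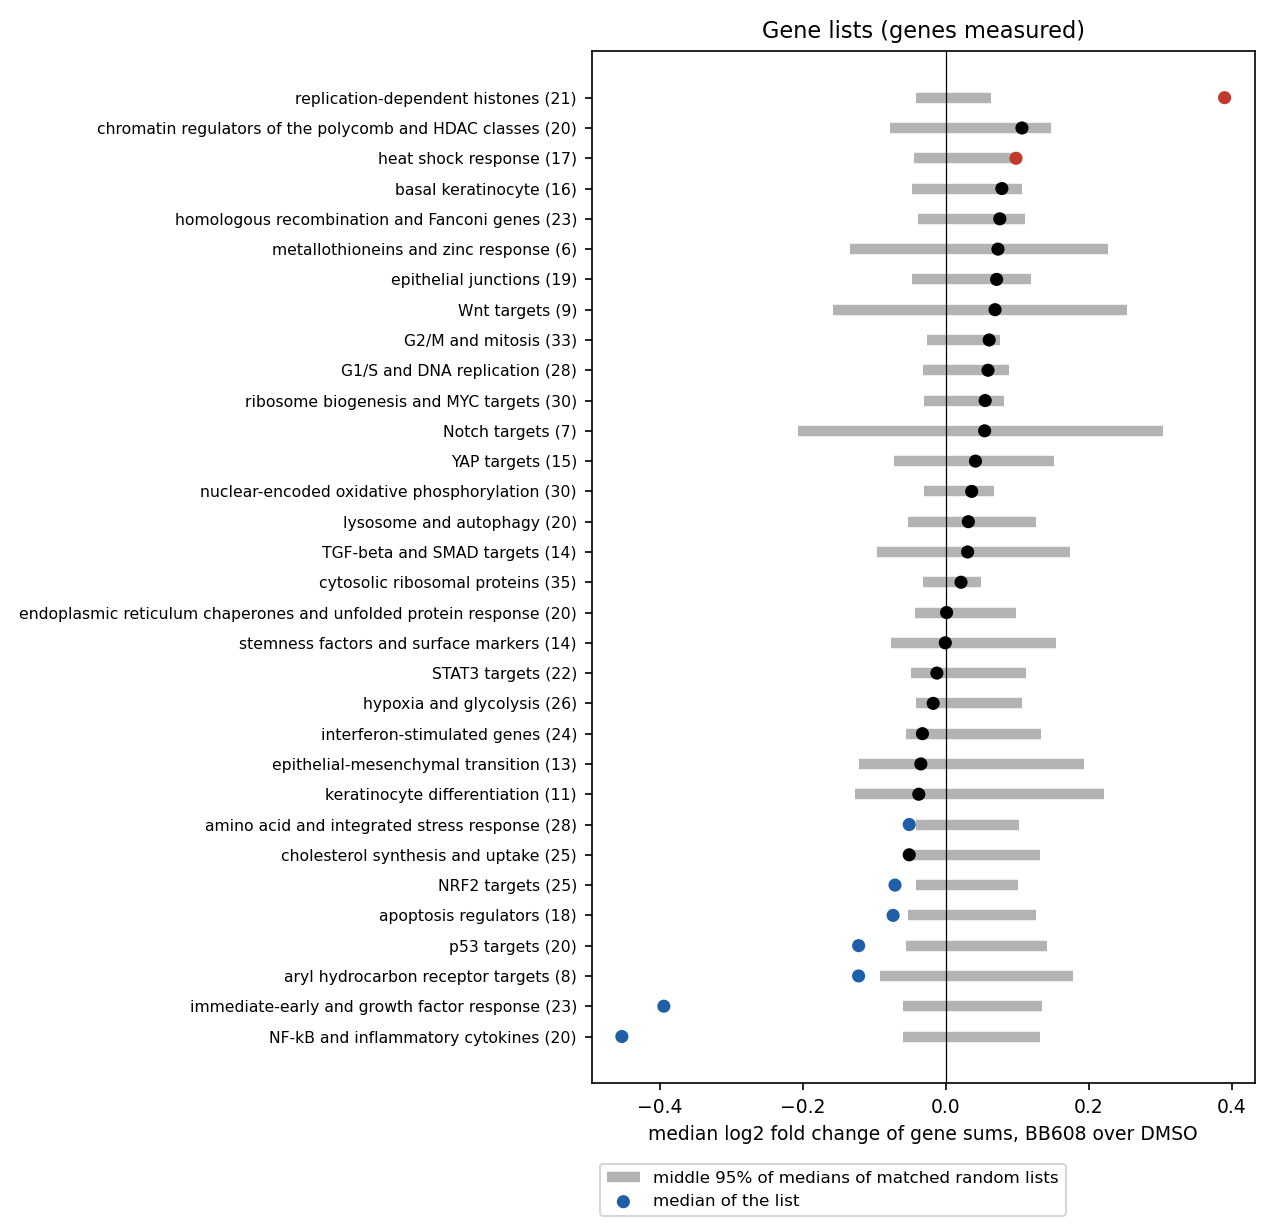
Median log2 fold change of gene sums, BB608 over DMSO (x axis), for each list with at least 5 kept genes (y axis, number of genes in parentheses). Grey bars hold the middle 95% of the medians of matched random lists; blue and red points lie below and above them, black points inside. The NF-kB list at -0.45, the immediate-early list at -0.39 and the histone list at 0.39 lie farthest out.

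Most of the genes named whatever their result were not called. STAT3 had a log2 fold of 0.26 (implied SE 0.19; p 0.164, q 0.997) for its most abundant coding sequence in the authors' deposited table, and 0.07 for its gene sum. Of its 5 tested coding sequences, others had 0.59 (p 0.023) and -0.68 (p 0.14) in that table, each with a q of 0.997. MYC had 0.06, SOX2 0.01, BMI1 -0.15, CD44 -0.05, ALDH1A3 0.35, BIRC5 -0.01 and CCND1 0.06 in that table. NQO1 had -0.08, HMOX1 -0.41, the keratinocyte transcription factor TP63 0.10 and the basal keratin KRT5 0.09. KLF4 had -1.60 with an implied SE of 1.13, a p of 0.218 and a q of 0.997 in the authors' deposited table. CDKN1A, the p53-induced cell cycle inhibitor, had -1.30 (implied SE 0.56) with an unadjusted p of 0.0286 and a q of 0.997 in the authors' deposited table. NANOG and ALDH1A1 had no tested coding sequence. Precision differed between these genes. The most abundant coding sequences of MYC, CCND1, BIRC5, TP63, KRT5 and NQO1 had implied SEs of 0.11 to 0.15. Changes of 1 log2 in these sequences lay far outside that error. Other tested coding sequences of these genes were less precise. Their implied SEs reached 1.46 for MYC, 1.33 for BIRC5, 1.77 for KRT5, 2.13 for CCND1 and 3.17 for TP63. A coding sequence of NQO1, at 0.568 FPKM in DMSO and 2.11e-07 FPKM in BB608, had no usable implied SE. No error was derived for gene sums. BMI1 had an implied SE of 0.69 and ALDH1A3 of 0.53, and for these a missed q does not show that they stayed level. SOX2 had 0.29 and CD44 0.31. The 19 tested coding sequences of CD44, none called, had folds from -2.57 (implied SE 1.57) to 4.12 (implied SE 4.60).

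The share of coding sequences called differed with how many tested ones a gene had. Genes with 1 tested coding sequence gave 81 calls among 3551 tested, or 2.28%, with a median implied SE of 0.24. Genes with more gave 41 calls among 30923, or 0.133%, with a median implied SE of 0.65. These shares are of coding sequences and not of genes, and abundance was not matched. The 81 calls include the 30 called histone cluster genes, each with 1 tested coding sequence.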

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

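The tests of shared reads, of length and GC content on histone genes, and of S phase were chosen only after the results were seen; that of length and GC content on immediate-early genes was set beforehand. Some coding sequences were not tested by the authors yet carry a signal in BB608 and are listed at 0 in DMSO in the authors' deposited table. RPS29, a cytosolic ribosomal protein gene, is listed at 2274 FPKM in BB608. LRR1, at the same locus, has coding sequences at 22.9 and 11.04 FPKM. AC012485.1 is listed at 44.3 FPKM and AC087239.1 at 12.6 FPKM. All 7 coding sequences of the RPS29 locus, on chromosome 14 from 50043390 to 50081390 of hg19, are listed at 0 in DMSO and carry the low data status. The 78 other ribosomal protein genes kept had log2 folds of gene sums from -0.49 to 0.88. A gene with a sum of 0 in either group could not be kept, so these genes do not show that RPS29 stands alone. No fold is given for the coding sequences listed at 0 in DMSO.

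The first pattern weighed is the joint rise of histone genes. Reads moved only among the 60 histone cluster genes would lower some of them, but all 60 were higher and the log2 ratio of their sum was 0.36. This value restates the pattern and leaves open reads from copies outside this set. Lists of other genes matched on transcript length and GC content had medians up to 0.12 at the upper bound of their middle 95%, against 0.39 for the histone genes. A larger share of cells in S phase stays open, because the G1/S and DNA replication list lay at percentile 86.71 of its random lists, high but inside their range. Differences between library preparations stay open too, since no value per library was analysed here.

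The second pattern is the joint fall of immediate-early genes. Random lists matched on transcript length and GC content reached a median of -0.044 at the lower bound of their middle 95%, against -0.39 for this list, which argues against these properties as the whole cause. These genes respond within a short time to medium change and handling, and such a difference between the groups was not tested and stays open beside an effect of BB608.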

How the results depend on the processing

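The alternatives with normal p-values, with single-sequence genes, with gene sums of named genes and with other summaries per gene for lists were chosen after seeing the data. No paired analysis was possible because the table holds 1 pooled value per group. For the same reason, leaving out each replicate, limma without the trend, library weights, fry and an estimated correlation were not run. Pseudocounts and scaling do not enter the authors' q, and filters do not alter a named fold.

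The 122 calls, 73 falls and 49 rises became 121, 71 and 50 with a mean FPKM of at least 1, and 83, 38 and 45 with at least 5, where fewer low-abundance sequences remain. A bound of 1 log2 left 40 calls, 33 falls and 7 rises by its own construction. Normal p-values gave 158 calls, 155 after scaling by the median of log2 ratios and 160 after quantile normalization, when 114 fell; the cause was not tested. Genes with 1 tested coding sequence, adjusted alone, gave 122 calls.

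Of 306 settings over 51 named folds, 272 stayed within 1 implied SE, 32 moved further and 2 reversed a called fold. The reversals came with gene sums, at 0.013 for RALGDS and 0.10 for NFIB; the cause was not tested. The uncalled folds of SOX2, under both scalings, and BIRC5, with the gene sum, changed sign near 0. A pseudocount of 1 moved 18 folds, and neither scaling moved any. Scaling by the median of log2 ratios shifted every fold by 0.0387, less than any implied SE among the named folds, so it could move none. The gene sum of a gene with 1 coding sequence equals its fold. Part of the 272 was therefore fixed in advance and does not measure stability. The number of lists that stood apart, 9, ran from 8 to 11, with at least 7 of the 9 shared. Heat shock was lost with pseudocounts of 0.1 and 0.01, no FPKM minimum, quantile normalization and the most abundant coding sequence, the integrated stress list with quantile normalization and apoptosis regulators with the most abundant coding sequence. Cholesterol synthesis was gained with a mean FPKM of at least 5, quantile normalization and the sum over tested sequences. That sum also gained epithelial-mesenchymal transition, and the most abundant sequence TGF-beta and YAP targets. The depth is unknown, so its effect was not assessed.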

Other observations

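The groups of genes here were chosen after their values were seen. Among dual-specificity phosphatases, which inactivate MAP kinases and other substrates, 4 of 16 genes fell, namely DUSP1, DUSP2, DUSP5 and DUSP10. The log2 folds of their gene sums were -1.33, -1.31, -0.83 and -0.77, while 7 of the 16 were higher in BB608. All 3 GADD45 genes were lower and 2 of them fell, GADD45A with a gene sum of -1.13 and GADD45B with -0.79. The called coding sequence of GADD45B had -1.39 in the authors' deposited table. Among 6 ligand genes of the lymphocyte receptor NKG2D, ULBP1 and ULBP2 fell, with gene sums of -0.82 and -0.54, and ULBP3 and RAET1G, not called, had -0.59 and -0.64. MICA and MICB were near level at -0.0015 and -0.11. TXNIP and ARRDC4, related arrestin-domain genes that respond to glucose, fell with gene sums of -0.48 and -0.52. CD274, which encodes the immune checkpoint ligand PD-L1, fell from 3.07 to 1.52 FPKM in the authors' deposited table. FASN, the fatty acid synthase gene, rose with a gene sum of 0.58.

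Replication-independent histone variants differed from the cluster genes in the number of calls, though 8 of 10 were higher in BB608. None of 10 was called by Cuffdiff's q, 2 had an unadjusted p under 0.05, and their gene sums ran from -0.02 to 0.30 with a median of 0.15, against 0.39 for the 60 cluster genes. The difference between both sets was not tested, and the sets were not matched on the number of tested coding sequences per gene. All 59 kept cluster genes had 1, and coding sequences of such genes were called more often, so the numbers of calls are not directly comparable.

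The mitochondrially encoded genes were nearly empty in the authors' deposited table. Of 13 coding sequences, 11 were under 0.1 FPKM in both groups, 9 were listed at 0 in DMSO, and 2 were tested. These were MT-ND6 at 4.40 and 3.28 FPKM and MT-ATP6 at 2.00 and 1.46 FPKM in DMSO and BB608. No level of mitochondrial transcripts can be read from such values. PRKDC, which encodes the DNA-dependent protein kinase, carried the failed status in all 4 of its coding sequences, with a summed FPKM of 44.5 in DMSO and 64.7 in BB608.

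Among called coding sequences of genes with several tested ones, 6 of 41 had a gene sum within 0.2 log2 of no change. These were RALGDS, NFIB, MORC4, SMPD4, PLEC and CSTF2. In 5 of the 6 the remaining coding sequences moved the other way, PLEC being the exception. Selecting genes by a nearly level sum largely fixes this direction in advance, so the count does not bear on a change of isoform. For RALGDS the called sequence went from 2.75 to 0.549 FPKM and the rest of the gene from 3.43 to 5.69 FPKM. A change of isoform and a different division of reads between overlapping sequences would give the same values.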
